A study of Mus musculus with 228 samples.

How the data were processed

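Gene expression was measured by RNA sequencing in 228 libraries of 10 mouse tissues. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a SMARTER mRNA kit. Per the submitters' processing notes, HISAT2 2.1.0, SAMtools 1.10 and StringTie 2.2.1 were used with the genome build GRCm39. The strandedness of the libraries, the sex of the mice, the hours of sampling and any library batches were not given in the sources used here. Genes of the Y chromosome were at 0 CPM (here without TMM scaling) in liver, hypothalamus, inguinal fat, cecum and spleen. Their highest level in the other tissues was 0.953 CPM, in mammary gland. In liver, Xist, an RNA of the inactive X chromosome in females, ran from 74.8 to 726 CPM. Antibiotics liver LD0/24 replicate 1, with 0 counts on chromosome X, is left out of this range. These values point to female mice. Without known strand, reads of a gene and of an overlapping antisense gene cannot be separated, and reads of near-identical paralogs, such as the Hba, Reg3 and Ugt1a genes, may have been split by the counting.

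The deposited values were treated as estimated counts per gene, since the submitters' processing notes name StringTie, which estimates abundances. They are whole numbers in 1 table of 46333 rows, and no rounding was needed. Values of 4, 8, 12 and 16 were in surplus: 146169 cells held 4, against 86362 with 3 and 66707 with 5. How these values came about was not given in the sources used here, so all tests were repeated on values divided by 4. In the table, 2 rows named no gene, took at most 0.114% of a library (median 0.00343%) and were left out of library totals and tests, and 6 rows with a repeated name were kept under their own names. Each column was matched to a library by its name, with 0 columns unmatched. Gene names were matched to the annotation of GRCm38.p6 only to learn which chromosome a gene lies on (44699 names matched and 1632 did not), and no coordinates are given.

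Groups were formed from the labelled tissue, diet and light cycle. The design text names 24 mice in each diet and cycle, each housed alone and aged 10 weeks, and the labels do not tie libraries of different tissues to the same mouse. Nothing states outright that the libraries of a group come from different mice, so p-values measure the spread between these libraries. Replicates were compared before use, and 3 cecum columns from different cycles were equal in all rows. As their true group cannot be known, all 3 were left out, which departs from the design fixed beforehand, where all libraries of a tissue enter the fit.

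Each tissue was fitted separately with edgeR 4.0.16 in R 4.3.3, on counts with TMM scaling, filterByExpr and a robust quasi-likelihood fit with 1 mean per diet and cycle. F tests asked whether the 5 chow groups were equal, whether the 5 antibiotics groups were equal and whether cycle effects differed between diets. Contrasts compared antibiotics with chow, averaged over cycles, and each cycle with LD12/12. P-values were two-sided and adjusted by Benjamini and Hochberg over all genes tested in a tissue, at a threshold of 0.05. Expression is given as CPM, counts relative to the TMM-scaled library size, as mean ± SD over libraries. Log2 fold changes are given as fitted, with a standard error (± SE). That error was derived as the absolute log2 fold change divided by the square root of the F statistic. It is approximate, above all for genes near 0 in 1 diet. Log2 CPM used a prior count of 2. A library counts as higher or lower in statements such as 30 of 30 when it lies above or below the chow mean of its cycle. The version of the quasi-likelihood fit was the default of this edgeR release. It was set after calls of both versions had been seen, and the other version is among the alternatives.

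The tests, their samples, the alternatives, the rule for named genes and 58 gene lists of pathways, cell types and quality measures were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists and contrasts of a tissue, and again with an estimated correlation. In each list called in the text with all libraries, the median and mean fold change and the test had the same sign. Of lists named but not called in colon, the absorption list had a median of -0.13 and a mean of -0.03 with the test upward, and the goblet cell list a median of 0.38 and a mean of 0.1 with the test downward. Members that passed were counted over all genes and with adjustment over the list alone. The genes named for the light cycle were the clock list members that passed, the 6 with the smallest F test p in a tissue, and the largest rises and falls of each contrast (3 of each, 5 in liver). The latter had to pass both tests, at a mean CPM of at least 2, with every library of the cycle on 1 side of every LD12/12 library. For antibiotics they were the 10 largest rises and 10 largest falls that passed at a mean CPM of at least 2 with the same direction in all 5 cycles. For the interaction they were the 6 with the smallest p, and for lists 2 to 4 members with the smallest adjusted p. Names of predicted genes and pseudogenes were left out of this choice, and the results of some genes it takes are not reported here. Other genes, such as Saa1, Cyp7a1, Cyp8b1, Csn2 and Wap, were chosen after their values were seen.

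The alternatives fixed beforehand were DESeq2 size factors, no expression filter, a filter at a mean CPM of 10, DESeq2 1.42.0, limma-voom, the replicate number as a block, chow libraries only and leaving out each library in turn. Alternatives added after the data had been seen were the other quasi-likelihood version, values divided by 4, covariates for the mitochondrial share, the library total, the clock genes (2 components) and, in colon, a Hox score (groups 10 to 13 minus groups 1 to 9), the 3 identical columns kept, and a fit without 16 libraries of doubtful quality. Those had a chromosome at 0, under 60% of the tissue's median number of detected genes, or at least 40% mitochondrial counts in a tissue with a median under 20%, or were among the identical columns. Correlations and score differences were tested with 100000 permutations.

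The fits were tested on simulated data with 200 changed genes, 100 at each fold size, drawn from the means and library sizes of the real libraries. For the chow light cycle, 2-fold and 4-fold changes were recovered in 68 and 94 of 100 genes in liver, 74 and 94 in hypothalamus, 67 and 93 in thymus, 4 and 64 in inguinal fat, 9 and 57 in cecum, and 5 and 51 in jejunum. The numbers were 0 and 17 in spleen, 0 and 9 in colon, 0 and 4 in mammary gland, and 0 and 1 in ileum. For antibiotics they were 97 and 99 in liver, 99 and 100 in hypothalamus, and 23 and 82 in colon. Library totals had tissue medians between 36.1 and 95.6 M counts, and totals and the spread between libraries were not varied apart in the simulation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.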

Results

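Messenger RNA was sequenced in 228 libraries from 10 tissues of C57BL/6N mice, an inbred laboratory strain, after 42 days under 1 of 5 light-dark cycles. The cycles were constant darkness (LD0/24), 8 h of light and 16 h of dark (LD8/16), 12 h of each (LD12/12), 16 h of light and 8 h of dark (LD16/8) and constant light (LD24/0). Liver was taken from chow-fed mice and from mice drinking water with antibiotics, with 6 libraries per cycle and diet. Hypothalamus and colon epithelium were taken from both diets with 3 libraries per cycle and diet. Inguinal white fat, ileum, jejunum and cecum epithelium, spleen, mammary gland and thymus came from chow-fed mice only, with 3 libraries per cycle in each of these tissues among those used. Library totals ran from 61.8 to 159 M counts (M, mega) in liver (median 93 M), 68.7 to 170 M in hypothalamus, 63.5 to 112 M in inguinal fat, 33 to 135 M in ileum and 8.92 to 133 M in colon. They ran from 86.2 to 154 M in jejunum, 61.7 to 157 M in cecum, 27.4 to 124 M in spleen, 7.2 to 93.3 M in mammary gland and 66.5 to 149 M in thymus. The cecum range includes the identical columns that were left out of the tests, at 61.72 M each.

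Mitochondrially encoded RNA, a measure that rises in damaged or cytoplasm-poor samples, took a median of 5.61% of counts in liver, 50.5% in colon and 86.2% in mammary gland. In spleen LD12/12, replicate 2 held 54.7% and replicate 3 held 50.5% mitochondrial counts, against a highest group mean of 6.54% at the other cycles. The LD12/12 jejunum libraries held 49.1 ± 40.4% (mean ± SD, n = 3). Milk genes took large shares in single libraries: Csn2, a milk casein, took 16.4% of counts in inguinal fat LD16/8 replicate 1, and Wap, a milk whey protein, took 30.2% in mammary gland LD24/0 replicate 1. In cecum, 3 columns, replicate 1 of LD0/24, LD8/16 and LD16/8, held identical values and were left out, which left 15 cecum libraries. One antibiotics liver library, LD0/24 replicate 1, held 0 counts on chromosomes 18, 19 and X and 0% mitochondrial counts. The plot of library totals and mitochondrial shares shows every library except the 3 identical cecum columns.

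**Figure D1:**
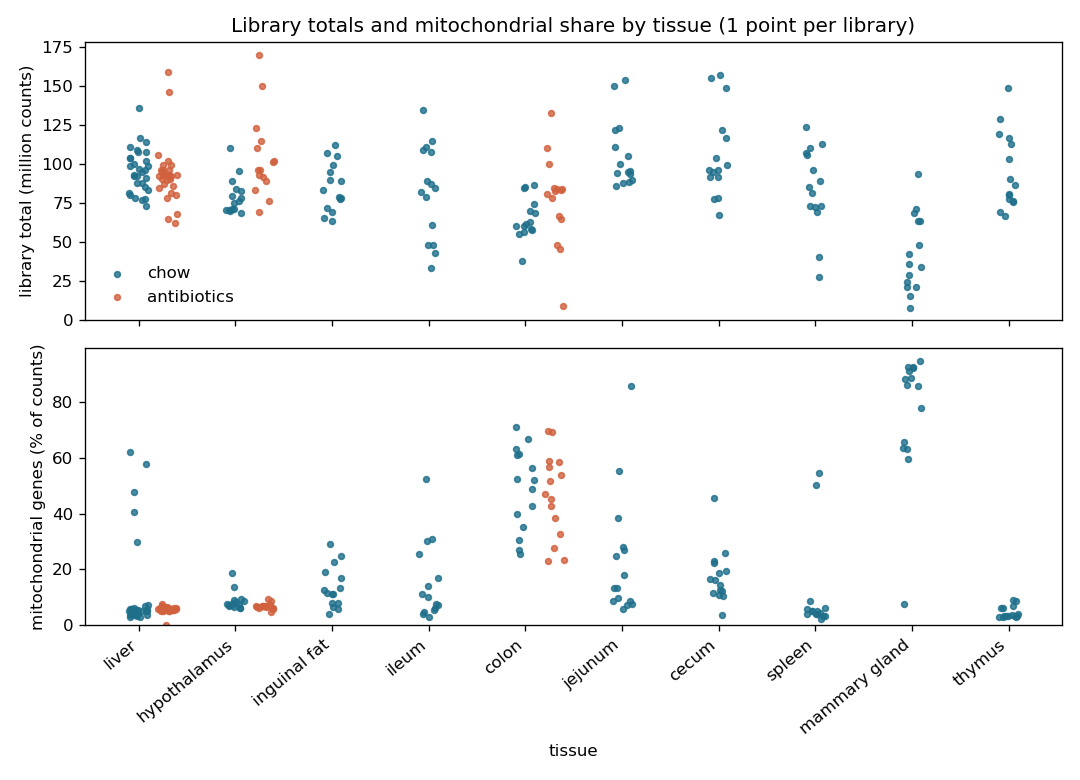
Library total in M counts and mitochondrial share in percent of counts for each library except the 3 identical cecum columns, by tissue, with chow libraries in blue and antibiotics libraries in orange. Mammary gland had the highest median mitochondrial share, 86.2%, and thymus the lowest, 3.41%.

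The first question was which genes differed in level among the 5 light cycles in chow-fed mice. In liver, 5 genes of neutrophil granules and cytosol differed: S100a9 and S100a8, which form calprotectin, Camp and Ngp, granule peptides, and Mpo, myeloperoxidase. S100a9 was at 33.3 ± 65.3 CPM at LD16/8 and 2.37 ± 0.92 CPM at LD12/12 (mean ± SD, n = 6), and Mpo at 7.05 ± 12.9 and 0.267 ± 0.198 CPM. Of 10 measured neutrophil genes 7 passed, and all 10 passed when adjusted over the list alone. Adjusted p was 0.00107 for S100a9, S100a8, Camp and Ngp and 0.00595 for Mpo. One library carried most of this signal: LD16/8 replicate 6 held 165 CPM of S100a9, against 1.69 to 24 CPM in the other 5 libraries of its group, and without it none of these 5 genes passed.

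Smc6, a subunit of a DNA repair complex, also differed in chow livers (adjusted p = 0.00529). Its mean was 7.25 ± 2.03 CPM at LD0/24, 9.27 ± 2.21 at LD8/16, 11.1 ± 3.84 at LD12/12, 13.6 ± 4.86 at LD16/8 and 16.3 ± 3.39 at LD24/0 (n = 6 each), so that the group means increased with the hours of light. The LD0/24 libraries lay between 4.75 and 10.5 CPM, and 5 of the 6 LD24/0 libraries between 16.8 and 18.4 CPM, with replicate 5, a library with 47.7% mitochondrial counts, at 9.49 CPM. Smc6 did not pass with limma-voom (adjusted p = 0.0559) or in a fit of the chow libraries alone (adjusted p = 0.905). Saa1 and Saa2, serum amyloid A genes of the acute phase response, passed as 2 of 20 measured acute phase genes (adjusted p = 0.0113 and 0.00996), and 4 passed when adjusted over the list alone.

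In all, 47 of 18971 liver genes passed the test over the 5 cycles in chow-fed mice, and 1545 had an unadjusted p under 0.05 where 949 would by chance. When the libraries were regrouped at random, 40 of 100 groupings, the real one included, called at least 47 genes. Chance therefore cannot be excluded for the liver calls. DESeq2 called 241 genes and limma-voom 0. A fit of chow libraries alone called 1 gene, and a fit with the replicate number as a block 0. Leaving out 1 library lowered the count to between 13 and 31 for 43 of 60 libraries and raised it to as many as 283 for 4 (without LD16/8 replicate 6). Leaving out the 5 libraries of doubtful quality, 4 with a high mitochondrial share on chow and 1 antibiotics library with chromosomes at 0, gave 549, of which 43 were among the 47.

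Spleen had 26 calls, with 2938 genes at an unadjusted p under 0.05, and 9 of its 13 mitochondrially encoded genes passed (all 13 when adjusted over the list alone). ND4, a subunit of respiratory complex I, was at 34600 ± 27800 CPM at LD12/12 and between 1020 ± 221 and 3910 ± 1380 CPM at the other cycles (n = 3, adjusted p = 0.0405). ND4 was at 55900 and 44700 CPM in the 2 LD12/12 libraries with over 50% mitochondrial counts and at 3240 CPM in replicate 1. The spleen count was 8348 without LD12/12 replicate 1. It was 0 without any 1 of the other 14 libraries. The count was also 0 without a filter, with limma-voom, with the replicate number as a block and with each covariate tried. DESeq2, the other quasi-likelihood version and values divided by 4 gave higher counts. In mammary gland the 3 calls were the globin genes Hba-a2, Hba-a1 and Hbb-bt, which red blood cells express. Hba-a2 was at 238 ± 95.3 CPM at LD0/24, 165 ± 67.9 at LD16/8 and 171 ± 62.6 at LD24/0, but 19.8 ± 10.7 at LD12/12 and 8.45 ± 7.89 at LD8/16 (n = 3, adjusted p = 2.23e-05). Simulated mammary libraries gave 21 false calls beside 4 of 100 genes recovered at 4-fold, so mammary calls cannot be relied on.

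No gene passed in the other 7 tissues with edgeR. The number of genes at an unadjusted p under 0.05 and the number called by DESeq2 were 1042 and 10 in hypothalamus, 1919 and 395 in inguinal fat, 419 and 36 in ileum, and 703 and 64 in colon. They were 1237 and 255 in jejunum, 1327 and 457 in cecum, and 1205 and 158 in thymus, and limma-voom called 0 in each of these tissues. By chance, 1228 genes would have an unadjusted p under 0.05 in hypothalamus, 1046 in inguinal fat, 1079 in ileum and 1186 in colon. The chance numbers were 1027 in jejunum, 1023 in cecum and 1114 in thymus. With simulated 4-fold changes, 94 of 100 genes were recovered in hypothalamus and 93 in thymus, but 9 in colon and 1 in ileum. Such changes were thus mostly missed in simulated ileum and colon libraries. In jejunum Aldoc, an aldolase of glycolysis, was at 15.5 ± 3.29 CPM at LD16/8 and 4.78 ± 1.3 CPM at LD12/12 (n = 3, adjusted p = 0.102). In colon Cox5a, a subunit of cytochrome c oxidase, was at 323 ± 16.1 CPM at LD12/12 and 57.4 ± 15.1 CPM at LD24/0 (adjusted p = 1), and it was among 13 genes that passed once the antibiotics colon library with the fewest detected genes (LD8/16 replicate 1) was left out of the joint fit.

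At the level of gene lists, 33 of 38 nuclear genes of oxidative phosphorylation fell in colon at LD24/0 relative to LD12/12 when adjusted over the list alone, and 0 when adjusted over all genes (camera adjusted p = 1.53e-39, adjusted p = 0.02 with an estimated correlation, median log2 fold change -1.27). The mitochondrial share of these chow colon libraries was 31.9 ± 9.57% at LD12/12 and 53.6 ± 2.45% at LD24/0 (n = 3). Genes of red blood cells were higher in thymus at LD8/16 (6 of 14 adjusted over the list alone, adjusted p = 8.12e-13, adjusted p = 0.00721 with an estimated correlation) and at LD16/8 (7 of 14, adjusted p = 6.47e-21, adjusted p = 0.00175 with an estimated correlation). The thymus level of Hba-a1, an alpha globin, was 58.5 ± 15.9 CPM at LD8/16, 60 ± 16.9 at LD16/8 and 19 ± 8.11 at LD12/12 (n = 3), and it did not pass over all genes. These were the only 3 list calls among the chow light cycle and antibiotics tests that held with an estimated correlation. With the preset correlation, 34 of 120 list and cycle pairs were called in liver, 24 of 104 in hypothalamus, 51 of 100 in inguinal fat, 57 of 120 in ileum and 66 of 116 in colon. The counts were 44 of 120 in jejunum, 45 of 116 in cecum, 49 of 96 in spleen, 24 of 100 in mammary gland and 32 of 96 in thymus.

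None of the 20 genes on the circadian clock lists passed over all genes with edgeR in any of the 10 tissues. In several tissues, liver among them, clock genes such as Dbp varied widely between libraries of a group. In hypothalamus, spleen and thymus the SD of Dbp within groups was only at the 51.3, 39.2 and 50.5 percentiles of all genes. Adjusted over the list alone, Bhlhe40 passed in jejunum and Nr1d1 in mammary gland (adjusted p = 0.685 and 0.692 over all genes). DESeq2 called Bhlhe40 in inguinal fat and jejunum, Arntl in spleen and Nr1d1 in mammary gland. Limma-voom called Nfil3, Nr1d1 and Usp2 in mammary gland and 0 clock genes in the other 9 tissues. In liver Dbp, a transcription factor driven directly by the clock, ran from 0.37 to 201 CPM, Arntl, which encodes the clock activator BMAL1, from 0.389 to 31.7 CPM, and Nr1d1, which encodes the repressor REV-ERB alpha, from 0.641 to 83.1 CPM. Chow LD0/24 livers held 111 ± 88.2 CPM of Dbp and chow LD12/12 livers 22.1 ± 7.73 CPM (n = 6, F test adjusted p = 0.944). The standard deviation of Dbp within groups was 2.99 on the log2 scale in liver and 0.35 in hypothalamus. The hours at which tissues were collected were not given in the sources used here.

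**Figure D2:**
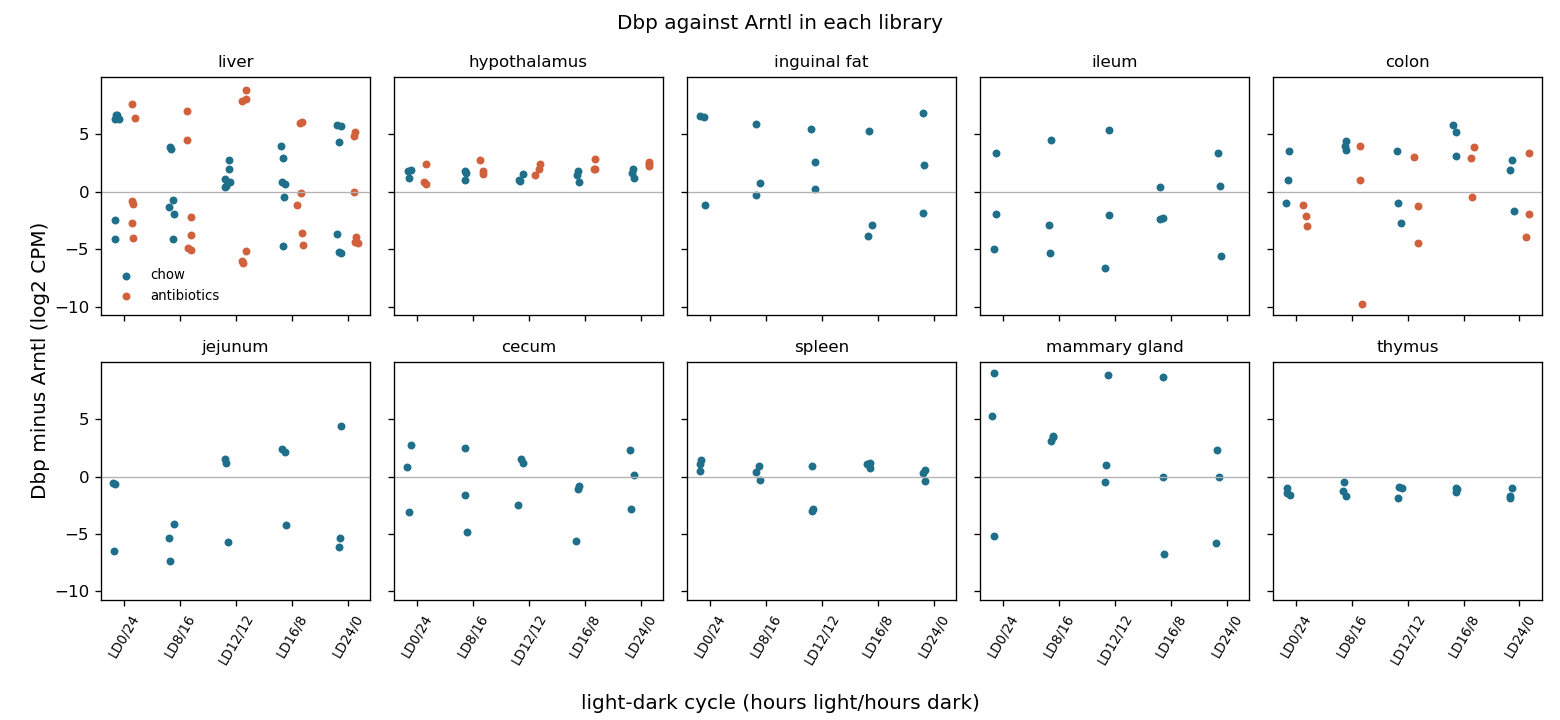
Log2 ratio of Dbp to Arntl CPM in each library, by light cycle and tissue, each point 1 library. In antibiotics livers at LD12/12 the 6 libraries lay at 7.9, 8.08, 8.84, -5.17, -6.01 and -6.21.

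Each cycle was also compared with LD12/12 in each tissue and diet. In inguinal fat 6 genes were called at LD0/24, named here after their values were seen: TrnH, TrnG, TrnS2, TrnL2 and TrnR, which encode mitochondrial transfer RNAs, and the predicted gene Gm10241 (adjusted p = 0.00666 to 0.0407). None of the 6 passed the test over the 5 cycles, where the smallest adjusted p was 0.0564. TrnH was at 18.6 ± 7.88 CPM, against 1.58 ± 0.759 CPM at LD12/12 (n = 3, log2 fold change 3.56 ± 0.45 SE, adjusted p = 0.0143). The mitochondrial share of these fat libraries was 22.1 ± 8.53% at LD0/24 and 8.04 ± 3.22% at LD12/12. The 6 calls became 0 without LD12/12 replicate 2 and with the library total as a covariate, 1 without LD12/12 replicate 1 or LD0/24 replicate 3, 3 without LD0/24 replicate 2, 11 without LD8/16 replicate 3 and 16 without LD0/24 replicate 1. In mammary gland Hba-a2 rose at LD0/24 (3.58 ± 0.61, adjusted p = 0.0095) and at LD16/8 (3.06 ± 0.6, adjusted p = 0.0265). Neither call held with limma-voom (adjusted p = 0.508 and 0.485) or without LD12/12 replicate 3. Besides Hba-a2, 4 genes were called lower in mammary gland at LD16/8. Of 52 such contrasts 46 had 0 calls with edgeR, and the others had 15 calls in all. DESeq2 had 0 calls in 2 contrasts and 16895 calls in all, limma-voom had 0 in 43 contrasts and 629 calls in all. Of 13014 genes tested in all 10 tissues, 0 passed over the 5 cycles in 2 or more tissues with edgeR, where 0.0716 would by chance, and DESeq2 called 10 genes in at least 5 tissues.

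The second question was how antibiotics changed expression, averaged over the 5 cycles. In liver, 2337 genes rose and 3225 fell among 18971. This split moved with the setting: 3125 rose and 3085 fell without the libraries of doubtful quality (4384 of the 5562 calls shared), 2862 and 2428 with limma-voom, and 2483 and 2577 with the mitochondrial share as a covariate. Cyp2b13, a female-biased cytochrome P450, rose by 3.27 ± 0.23 on the log2 scale (SE), from 23.8 ± 18.4 to 219 ± 89.3 CPM (n = 30 per diet, adjusted p = 2.65e-16), and lay above the chow mean of its cycle in 30 of 30 antibiotics libraries. Hamp, the iron hormone hepcidin, rose from 309 ± 218 to 937 ± 201 CPM (1.61 ± 0.21, adjusted p = 3.84e-08, 30 of 30 higher). Serpina7, thyroxine-binding globulin, rose by 2.49 ± 0.32 (27 of 30 higher), H19, an imprinted noncoding RNA, by 2.82 ± 0.29 (29 of 30), and Ildr2, Pcp4l1, Adgrf1, Dsg1c, Ntrk2 and Tcf24 rose by 1.49 to 2.49. Fabp5, a fatty acid binding protein, fell by 3.11 ± 0.23, from 549 ± 287 to 65.6 ± 51.6 CPM (adjusted p = 5.89e-16, 30 of 30 lower). G6pdx, which opens the pentose phosphate pathway, fell by 3.21 ± 0.28, from 54 ± 34.9 to 5.8 ± 2.94 CPM (30 of 30 lower). Antibiotics LD0/24 replicate 1 held 0 counts on chromosome X, so for X-linked genes such as G6pdx and Serpina7 it counts as lower for that reason. Rims4, BC049987, Pla2g4f, Chrna4 and Adcy1 fell, with log2 changes of -4.04 to -3.26, each in 30 of 30 libraries, and Ugt1a10, a glucuronosyltransferase whose reads can be shared with other Ugt1a genes, fell in 27 of 30 but did not pass with limma-voom (adjusted p = 0.114). Smc6 rose by 0.71 ± 0.09 to 18.2 ± 2.05 CPM (adjusted p = 6.55e-09).

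Lipid synthesis genes fell together in antibiotics livers. Of 25 cholesterol synthesis genes 21 fell and 0 rose (21 adjusted over the list alone), with Mvd at -1.73 ± 0.16, Fdps at -1.48 ± 0.12, Hmgcs1 at -1.41 ± 0.21 and Dhcr7 at -1.18 ± 0.1 (camera adjusted p = 2.18e-16, adjusted p = 0.183 with an estimated correlation). Of 22 lipogenesis genes 15 fell and 0 rose (16 adjusted over the list alone), with Elovl6, a fatty acid elongase, at -2.13 ± 0.24 and Fasn, fatty acid synthase, at -1.76 ± 0.18, from 2740 ± 1020 to 820 ± 535 CPM (adjusted p = 1.34e-15, adjusted p = 0.0728 with an estimated correlation). Of 25 genes of fatty acid oxidation and PPAR alpha targets 10 rose and 1 fell (11 and 1 adjusted over the list alone), with Cyp4a14 at 1.4 ± 0.25 and Acadl at 0.34 ± 0.06 (adjusted p = 0.00165, adjusted p = 0.915 with an estimated correlation). Cyp8b1, the sterol 12-hydroxylase that sets the share of cholic acid, fell by 1.81 ± 0.22 (adjusted p = 5.25e-09), while Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -0.29 ± 0.21 (adjusted p = 0.315), and the list of 22 bile acid genes was not called (6 rose, 2 fell).

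Genes of several other cell types also differed by diet in liver. All 10 measured neutrophil genes fell (adjusted p = 2.75e-11, adjusted p = 0.177 with an estimated correlation), with S100a9 going from 9.5 ± 29.8 to 0.69 ± 0.419 CPM, and Camp, at 1.91 ± 6.96 and 0.00635 ± 0.0155 CPM, was at 0 in most antibiotics livers, so that its fitted fold change depends on the prior count. Without chow LD16/8 replicate 6, which held 165 CPM of S100a9 and 38.1 CPM of Camp, the chow means were 4.12 ± 4.47 and 0.662 ± 1.36 CPM (n = 29), and all 10 genes still fell (adjusted p = 1.64e-12). Of 12 red blood cell genes 10 fell (11 fell and 1 rose adjusted over the list alone), with Hba-a2 at -1.83 ± 0.19 (adjusted p = 4.48e-09, adjusted p = 0.0685 with an estimated correlation). Of 12 T cell genes 7 rose and 0 fell (9 adjusted over the list alone), with Trac at 0.64 ± 0.19 (adjusted p = 0.000329, adjusted p = 0.646 with an estimated correlation). Of 27 cell cycle genes 22 fell (23 adjusted over the list alone), with Mki67, a proliferation marker, at -1.77 ± 0.2 (adjusted p = 1.8e-09, adjusted p = 0.6 with an estimated correlation). Of 25 interferon response genes 16 fell (18 adjusted over the list alone), with Irf7 at -0.9 ± 0.09 (adjusted p = 1.72e-07, adjusted p = 0.493 with an estimated correlation). Of 13 mitochondrially encoded genes 12 fell (13 adjusted over the list alone, adjusted p = 0.0167, adjusted p = 0.946 with an estimated correlation), and the mitochondrial share was 5.65 ± 1.22% with antibiotics and 12 ± 16.9% on chow (n = 30 each, medians 5.66% and 5.15%). This difference rested on 5 chow libraries with 30, 40.6, 47.7, 57.8 and 62% mitochondrial counts. Without the libraries of doubtful quality, 4 of these 5 and 1 antibiotics library, the share was 5.84 ± 0.595% with antibiotics and 5.84 ± 5.05% on chow, 0 of the 13 genes passed and the list was not called (adjusted p = 0.743). Ribosomal protein genes (12 of 36 fell, 12 adjusted over the list alone) and xenobiotic metabolism genes (7 rose and 12 fell of 30, 8 and 12 adjusted over the list alone) were also called downward, at adjusted p = 0.0142 and 0.0305 and adjusted p = 0.946 and 0.646 with an estimated correlation. Without the libraries of doubtful quality the xenobiotic list was not called (adjusted p = 0.175).

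**Figure D3:**
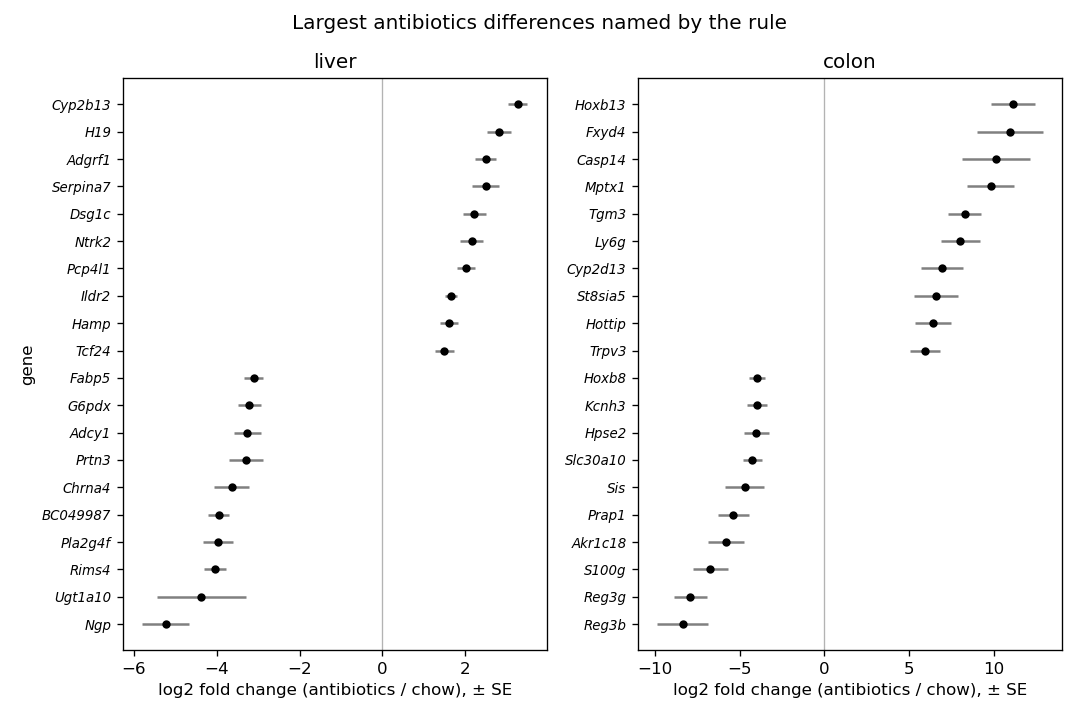
Log2 fold change, antibiotics over chow, of the 10 named genes that rose most and the 10 that fell most in liver and colon, with bars for the standard error derived from the F statistic. In liver the changes of rising genes ran from 1.49 (Tcf24) to 3.27 (Cyp2b13), and those of colon genes near 0 in 1 diet depend on the prior count.

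In hypothalamus 1316 genes rose and 1951 fell among 24557 with antibiotics, mostly by small amounts. With 1 library left out, the rises ran from 873 to 2663 and the falls from 1041 to 3042, so this split depended on the libraries kept. Kiss1, the kisspeptin neuropeptide, rose from 2.08 ± 1.35 to 4.5 ± 2.53 CPM (n = 15 per diet, log2 fold change 1.16 ± 0.29, adjusted p = 0.0111, higher in 12 of 15). Rbm3, a cold-inducible RNA-binding protein, rose from 40.6 ± 9.99 to 74.7 ± 20.3 CPM (0.9 ± 0.12, adjusted p = 0.000106, higher in 14 of 15), and Gbp4, an interferon-inducible GTPase, by 0.99 ± 0.12 (adjusted p = 2.25e-05, higher in 15 of 15). Cyp3a13, Slc38a5, Bc1, Gp1bb and Egfl8 rose by 0.88 to 1.19. S100a9 fell from 3.78 ± 2.23 to 0.848 ± 0.63 CPM (adjusted p = 0.00166, lower in 15 of 15). Kcna3, a potassium channel, fell by 2.15 ± 0.48 (15 of 15 lower), and Plcxd3, Hs6st3, Lnpep, Xylt1, Ksr2, Ankfn1 and Chrm5 fell, with log2 changes of -1.95 to -1.39. With the library total as a covariate Kiss1, Bc1, Kcna3 and these 7 genes did not pass, and Hs6st3, Lnpep, Ksr2 and Chrm5 did not pass with limma-voom. Chrm5 also lost its call without a filter and in 23 of 30 fits that left out 1 library.

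Of 17 heat shock genes 10 fell and 0 rose in antibiotics hypothalami (11 fell and 1 rose adjusted over the list alone), with Hsph1 at -0.43 ± 0.07 (camera adjusted p = 1.06e-06). Of 18 endoplasmic reticulum stress genes 6 fell and 1 rose (10 and 1 adjusted over the list alone), with Hsp90b1 at -0.39 ± 0.05 (adjusted p = 0.000923), and of 25 cholesterol synthesis genes 7 rose (8 adjusted over the list alone), with Mvk at 0.32 ± 0.04 (adjusted p = 0.000657). The p with an estimated correlation was 0.911 for each of these 3 lists. Adjusted over the list alone, 6 endothelial genes rose and 1 fell, 6 ribosomal and 2 myelin genes rose, and 1 gene of oxidative phosphorylation fell. Over all genes, endothelial genes (6 of 12 rose, 1 fell, adjusted p = 0.0208), ribosomal protein genes (6 of 36 rose, adjusted p = 5.28e-06), myelin genes (2 of 12 rose, adjusted p = 0.025) and nuclear genes of oxidative phosphorylation (2 of 38 rose, 1 fell, adjusted p = 0.0167) were called upward, with p between 0.934 and 0.996 with an estimated correlation. Of 13 mitochondrially encoded genes 7 fell (12 adjusted over the list alone, adjusted p = 9.15e-09, adjusted p = 0.911 with an estimated correlation), and the mitochondrial share was 6.8 ± 1.14% with antibiotics and 8.72 ± 3.35% on chow. Library totals also differed by diet, at 104 ± 26.8 M with antibiotics and 79.5 ± 11.6 M on chow (n = 15 each). The 3267 calls became 1158 with the library total as a covariate, of which 921 were among the 3267. They became 8515 with the mitochondrial share (4191 higher and 4324 lower), of which 3181 were among the 3267. With 1 library left out the calls ranged from 2052 without chow LD12/12 replicate 1 to 5705 without chow LD12/12 replicate 3, with 2104 without antibiotics LD0/24 replicate 2 and 4908 without chow LD16/8 replicate 1.

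In colon epithelium 271 genes rose and 490 fell among 23717. With 1 library left out, the rises ran from 175 to 584 and the falls from 311 to 827. Reg3b and Reg3g, antibacterial lectins induced by microbes, fell from 115 ± 96.3 to 1.13 ± 2.08 CPM and from 48.6 ± 41.1 to 0.465 ± 0.783 CPM (n = 15 per diet, adjusted p = 0.00225 and 3.26e-05, lower in 15 of 15 each). S100g, a calcium-binding protein of absorptive cells, fell from 468 ± 399 to 5.58 ± 7 CPM and Prap1 from 88.1 ± 57.3 to 7.5 ± 16.7 CPM, and Slc30a10, a manganese exporter, fell by 4.24 ± 0.57 (15 of 15 lower each). Hoxb13, a marker of the most distal gut, rose from 1.06 ± 4 to 85.4 ± 97 CPM (adjusted p = 2.88e-05, higher in 15 of 15), and Tgm3, a transglutaminase, from 1.52 ± 4.07 to 267 ± 335 CPM (adjusted p = 1.16e-05, 15 of 15). Mptx1, a pentraxin, was at 11 ± 42 CPM on chow and 625 ± 630 CPM with antibiotics (adjusted p = 0.000187, 13 of 15 higher), and Fxyd4, Casp14, Ly6g, Cyp2d13, St8sia5, Hottip and Trpv3 were below 0.3 CPM on chow and between 6.78 and 27.5 CPM with antibiotics. These 7 genes lay above the chow mean of their cycle in 9 (Casp14, St8sia5) to 14 (Ly6g, Hottip) of 15 antibiotics libraries. Fxyd4 and Casp14 did not pass without antibiotics LD0/24 replicate 3 or LD8/16 replicate 3 (adjusted p = 1 each), nor St8sia5 with limma-voom or the block (adjusted p = 0.0868 and 0.104). The fitted fold changes of these genes depend on the prior count, since many chow libraries held 0. Hoxb8, Akr1c18, Sis, Hpse2 and Kcnh3 fell, with log2 changes of -5.79 to -3.97, and Sis did not pass without a filter (adjusted p = 0.0731).

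Several gene lists were called in colon at the preset correlation, and none of these calls held with an estimated correlation. The list of 27 absorption genes was not called (5 rose and 3 fell, 6 and 7 adjusted over the list alone, adjusted p = 0.655, adjusted p = 0.91 with an estimated correlation). Of 15 genes of butyrate use and ketogenesis 6 fell and 1 rose (the same numbers adjusted over the list alone), with Pparg, a nuclear receptor of lipid metabolism, at -1.72 ± 0.34 and Oxct1 at 0.83 ± 0.16 (camera adjusted p = 1.16e-06). Of 21 xenobiotic metabolism genes 9 fell and 1 rose (14 and 1 adjusted over the list alone), with Cyp2c55 going from 1010 ± 673 to 112 ± 192 CPM (adjusted p = 5.42e-10, adjusted p = 0.117 with an estimated correlation). Of 11 enteroendocrine genes 5 fell and 1 rose (7 and 2 adjusted over the list alone), with Tph1, which makes gut serotonin, at -2.43 ± 0.35 and Chga at -1.69 ± 0.33 (adjusted p = 2.1e-07, adjusted p = 0.0601 with an estimated correlation). Of 12 bile acid response genes 3 fell (5 adjusted over the list alone), among them the bile acid transporter Slc10a2 at -3.52 ± 0.85 (adjusted p = 0.00228), and of 25 interferon response genes 4 fell (5 adjusted over the list alone), with Irf7 at -1.59 ± 0.31 (adjusted p = 8.24e-07, adjusted p = 0.442 with an estimated correlation). Of 8 MHC class II genes 3 rose (6 adjusted over the list alone, adjusted p = 1.86e-07), with H2-Aa at 1.24 ± 0.29. Of 36 ribosomal protein genes 8 rose (27 adjusted over the list alone, adjusted p = 2.21e-21), and of 5 Paneth cell genes Ang4 rose by 3.91 ± 0.66 (3 adjusted over the list alone, list adjusted p = 0.00212). B cell genes were called upward with 0 of 12 passing over all genes and 11 when adjusted over the list alone (adjusted p = 1.01e-08, median 2.3). Their mean lay above the chow mean of the cycle in 9 of 15 antibiotics libraries, and with a Hox score as a covariate the list turned downward (adjusted p = 2.82e-07). Collagen genes were called downward with 0 of 17 passing (adjusted p = 0.0133, adjusted p = 0.713 with an estimated correlation). The p with an estimated correlation was 0.422 for the ketogenesis, bile acid, MHC class II, ribosomal, Paneth and B cell lists.

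Hox genes, which mark position along the gut, differed by diet in the colon libraries. Of 7 genes of Hox groups 10 to 13 measured, 4 rose and 2 fell, and of 20 genes of groups 1 to 9, 0 rose and 8 fell. A score of distal minus proximal Hox genes was 1.12 ± 1.16 with antibiotics and -1.82 ± 0.65 on chow (log2, n = 15 each, two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). With this score as a covariate 0 of the 761 colon genes passed, at a smallest adjusted p of 0.233 with 1847 genes at an unadjusted p under 0.05, and the fitted changes of Casp14, Cyp2d13, Reg3b, Sis, St8sia5 and Trpv3 turned their sign. Leaving out LD8/16 replicate 1, an antibiotics library with 4225 detected genes, gave 1411 calls, of which 734 were among the 761, and DESeq2 called 1729.

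Within antibiotics-fed mice few genes differed among the 5 cycles. In hypothalamus Tph1, Chrnb4, Gpr151 and Rbp3, genes known from the pineal gland and the habenula, passed (adjusted p = 0.033 to 0.0333). All 4 lost their call without a filter, with limma-voom, with the block and with the library total or the clock components as covariates, and in 20 (Tph1), 22 (Chrnb4) and 24 (Gpr151, Rbp3) of 30 fits that left out 1 library. Gpr151 and Rbp3 also lost it with the mitochondrial share as a covariate. Tph1 was at 10.4 ± 16.9 CPM at LD16/8, with 29.9 CPM in replicate 3, and at 0.246 ± 0.111 CPM or less at the other cycles (n = 3), and Gpr151 was at 27.9 CPM in replicate 2 of LD16/8. In liver Ugt1a8 passed (adjusted p = 0.0425) with 24.2 CPM in LD16/8 replicate 6 and 0 in the other 5 libraries of that group. It lost its call in 36 of 60 fits that left out 1 library. It also lost it without the libraries of doubtful quality, without a filter, with limma-voom, with the block and with the library total or the clock components as covariates. In colon 5 genes passed: AY036118, LOC118568312, Lars2, Rn7s1 and Rn7s2. Lars2, annotated as a mitochondrial leucyl-tRNA synthetase, was at 487000 CPM in LD8/16 replicate 1, the colon library with the fewest detected genes. Whether these reads come from the synthetase messenger RNA was not tested, and 0 genes passed without that library. Limma-voom called 0 genes in liver and hypothalamus and 33 in colon. DESeq2 and the other quasi-likelihood version called more genes than edgeR in each of these tissues.

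The last question was whether the effect of the light cycle differed between diets. No gene passed the interaction test with edgeR, and 933 genes in liver, 922 in hypothalamus and 1055 in colon had an unadjusted p under 0.05. The numbers that chance would give were higher, at 949, 1228 and 1186. Smc6 ranked first in liver, at an adjusted p of 0.809. Its antibiotics means were 19.8 ± 1.46 CPM at LD0/24 and 17.6 ± 2.65 CPM at LD24/0 (n = 6). DESeq2 called 3 genes in liver, 1 in hypothalamus and 8 in colon, and limma-voom 0 in each. With simulated 4-fold interactions, 84 of 100 genes were recovered in liver, 89 in hypothalamus and 0 in colon, so such differences were not detectable in simulated colon libraries.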

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

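Among the tests in this part, those of the Hox score, of Dbp against Arntl, of equal replicate numbers, of neutrophil genes without libraries of doubtful quality and of RNA quality in tissues other than liver were chosen only after the result was seen, as were the bound on fold and error used to weigh the Hox covariate and the fits with the library total, the mitochondrial share or the Hox score as a covariate.

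Of 90 combinations of a measure and a group of 6 liver libraries, 28 held a library far from the others by its gap relative to the range, where chance gives about 1 in 20 groups. That rate does not apply here: 20 of the 28 concern 6 genes chosen because they passed in liver, 5 of which are neutrophil genes that rose together in 1 library, and in some antibiotics groups Camp, Ngp or Mpo was at 0 in the other 5 libraries. The other 8 concern 3 measures of a library. The antibiotics LD0/24 replicate 1 lay apart by its library total of 64.7 M counts, its 17219 detected genes and its 0% mitochondrial counts. Chow LD8/16 replicate 3 lay apart with 17126 detected genes and 40.6% mitochondrial counts, and chow LD12/12 replicate 2 (62%), chow LD24/0 replicate 5 (47.7%) and antibiotics LD16/8 replicate 6 (7.06%) by their mitochondrial share. Smc6 lay apart at 9.49 CPM in chow LD24/0 replicate 5 and at 22.6 CPM in antibiotics LD24/0 replicate 6.

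Chow LD16/8 replicate 6 lay far above its group in S100a8 (139 CPM), S100a9 (165), Camp (38.1), Ngp (108) and Mpo (32.4). Chow LD24/0 replicate 2 lay apart in S100a8 (7.3 CPM) and S100a9 (10.8), and chow LD0/24 replicate 5 in Ngp (3.09) and Mpo (1.24). Antibiotics livers lay apart at low levels: S100a8 at 2 CPM in LD16/8 replicate 1, Camp at 0.037 in LD0/24 replicate 6, 0.0277 in LD12/12 replicate 4 and 0.019 in LD24/0 replicate 2, Ngp at 0.107 in LD0/24 replicate 4 and 0.115 in LD24/0 replicate 1, and Mpo at 0.0569 in LD0/24 replicate 1, 0.0461 in LD12/12 replicate 4 and 0.0647 in LD16/8 replicate 1.

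Liver neutrophil genes past the chow light cycle test may rest on a single library: leaving out LD16/8 replicate 6 ended all 5 calls, while leaving out any other liver library ended none. That all 5 genes still passed without the libraries of doubtful quality decides nothing on RNA quality, since this library, with 2.94% mitochondrial counts and 20235 detected genes, was not among them. What set that library apart, such as RNA quality, inflammation of the mouse or blood left in the tissue, stays open. With the other 5 LD16/8 libraries kept and this one left out, 0 of the 5 genes passed, which does not show that the LD16/8 cycle had no effect.

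The antibiotics effect in colon came with a Hox score 2.94 higher on the log2 scale than on chow, which is consistent with the antibiotics samples having been taken nearer the distal end of the colon. With the Hox score as a covariate 0% of the calls were left, but the median absolute log2 fold change of the called genes only went from 2.29 to 1.39 while their median standard error went from 0.48 to 1.05 (variance inflation 3.77), so the calls ended partly because score and diet overlap. Among called genes the slope on the score within groups correlated with the antibiotics effect across genes at 0.64, against 0.18 over all genes, and genes are not independent replicates. Position and a biological effect of antibiotics therefore cannot be told apart for the colon genes, while 753 of the 761 genes passed with the library total as a covariate (1738 calls, 228.4% of the number without it) and 728 with the mitochondrial share (885 calls, 116.3%), so neither accounts for them as the whole cause. An effect of antibiotics on Hox genes themselves was not tested.

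For antibiotics in liver, the number of calls was 102.2% of that without a covariate with the library total (5328 of the 5562 genes shared) and 91% with the mitochondrial share (4563 shared), and in hypothalamus 35.4% (921 of the 3267 shared) and 260.6% (3181 shared). In hypothalamus, library total and diet cannot be told apart for the calls lost with the total as a covariate, since both differ between the same libraries. The labels name 0 batches, so whether libraries of both diets were made together was not tested in the 3 tissues.

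In liver, Dbp and Arntl varied more between libraries of 1 group than most genes did, with SDs within groups at the 99.9 and 98.9 percentiles of all genes. Poor RNA, as measured by the mitochondrial share, is argued against in liver, where the Dbp to Arntl ratio showed r = 0.04 with that share (n = 60, rho = -0.02, permutation p = 0.841 and 0.832, adjusted p = 0.978 over a family of 10 tissues, r = -0.01 without the 2 farthest libraries), but it stays open in the other 9 tissues. There the absolute r was over 0.3 in 3, jejunum, cecum and spleen, while without the 2 farthest libraries it was over 0.3 in jejunum (r = 0.31), spleen (-0.62), inguinal fat (-0.39) and mammary gland (0.4) and not in cecum (-0.05). Dbp and Arntl, which peak at opposite times of day, went in opposite directions within groups with r under -0.5 in 7 of 10 tissues, as would be seen if libraries of a group were collected at different clock times or if clocks of different mice had drifted apart. Of 10 tissues, 2 held more clock gene variance in 2 components than 95% of random lists (85% in liver and 83.3% in inguinal fat), a test that decides nothing, because random lists held over 50% in 2 components in every tissue. Equal replicate numbers did not share a clock time across tissues (median r = -0.03 over tissue pairs). Antibiotics livers at LD12/12, which had a daily light-dark cycle, lay at log2 ratios of 7.9, 8.08, 8.84, -5.17, -6.01 and -6.21. For these livers the values argue against drift in the absence of a daily cycle. Chow livers lay between 0.46 and 2.8 at LD12/12 and between -4.12 and 6.72 at LD0/24. Livers at LD8/16 and LD16/8, which also had a daily cycle, spread widely as well. Chow livers lay between -4.1 and 3.94 at LD8/16 and between -4.75 and 4.03 at LD16/8. Antibiotics livers lay between -5.05 and 7.01 and between -4.65 and 6.05 at these cycles. For the LD8/16 and LD16/8 livers the values also argue against drift in the absence of a daily cycle. In constant darkness and constant light, collection times and clock drift cannot be told apart without the hours of sampling. The other tissues were not weighed in this way.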

How the results depend on the processing

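The tests with the other quasi-likelihood version, with values divided by 4, with covariates, with the identical cecum columns kept and without the doubted libraries were chosen only after the result was seen, and the others were chosen before the data were examined. The antibiotics effect kept its order of size under most alternatives: liver calls lay between 5060 and 6220 under every alternative but a mean CPM of at least 10, where fewer genes were tested and 2834 passed. Where the count of genes that differed among the light cycles was above 0 (liver, spleen and mammary gland on chow and all 3 tissues with antibiotics), it moved by more than 1.5 times under most alternatives, and none of these counts held under all of them. Counts of 0 on chow stayed at 0 under most alternatives except in inguinal fat, and in hypothalamus and ileum under all but DESeq2. Where no cause is given for a count that moved, the cause was not tested. DESeq2 gave a higher count than edgeR in each of the light cycle and interaction tests. Depth limits which genes could be tested: the shallowest libraries held 7.2 M counts in mammary gland and 8.92 M in colon, and genes below the expression filter were not tested there.

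With DESeq2 the antibiotics effect in colon had 1729 calls in place of 761, 699 of them among the 761. The interaction had 3 calls in liver, 1 in hypothalamus and 8 in colon in place of 0, and 10 genes in place of 0 passed for the light cycle in at least 5 tissues. For the light cycle with antibiotics DESeq2 called 141 genes in liver (edgeR 1), 118 in hypothalamus (edgeR 4) and 224 in colon (edgeR 5). For the light cycle on chow it called 241 in liver (edgeR 47), 10 in hypothalamus, 395 in inguinal fat, 36 in ileum, 64 in colon, 255 in jejunum, 457 in cecum and 158 in thymus (edgeR 0 in each), 2311 in spleen (edgeR 26) and 85 in mammary gland (edgeR 3). Limma-voom called 0 genes on chow in liver and spleen and 560 in mammary gland, and with antibiotics 0 in liver, 0 in hypothalamus and 33 in colon. The other quasi-likelihood version gave 1272 calls for antibiotics in colon, 38, 14 and 40 for the light cycle with antibiotics in liver, hypothalamus and colon, and on chow 90 in liver, 54 in inguinal fat, 2 in jejunum, 2 in cecum, 438 in spleen and 7 in mammary gland.

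Of the counts over the 5 cycles and between diets, DESeq2 size factors moved that of mammary gland alone, to 8. With a mean CPM of at least 10, 485 genes passed for antibiotics in colon, 0 for the light cycle with antibiotics in liver and hypothalamus, and on chow 11 in liver, 1 in inguinal fat and 5 in mammary gland. Without an expression filter, where more genes were tested, the light cycle with antibiotics had 0 calls in liver, 0 in hypothalamus and 13 in colon, and the light cycle on chow 22 in liver, 3 in inguinal fat, 43 in mammary gland and 0 in spleen. Values divided by 4 gave 0 calls in liver and 12 in colon for the light cycle with antibiotics, and 60 in spleen and 12 in mammary gland on chow. A fit of chow libraries alone gave 1 call in liver, with fewer libraries to estimate the spread, and 53 in colon.

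The library total as a covariate gave 1158 calls for antibiotics in hypothalamus and 1738 in colon, 0 for the light cycle with antibiotics in all 3 tissues and 0 on chow in spleen. The mitochondrial share gave 8515 for antibiotics in hypothalamus, of which 3181 were among the 3267, 3 in liver and 0 in colon for the light cycle with antibiotics, and 5 in cecum, 0 in spleen and 1 in thymus on chow. The clock components gave 0 for the light cycle with antibiotics in all 3 tissues and, on chow, 16 in liver, 5 in inguinal fat, 0 in spleen and 1 in mammary gland. The Hox score gave 0 for antibiotics and 0 for the light cycle with antibiotics in colon. With it the log2 fold change turned to -3.03 for Casp14, -0.21 for Cyp2d13, -0.71 for St8sia5, -0.68 for Trpv3, 0.09 for Reg3b and 3.86 for Sis, and the colon B cell list turned downward (adjusted p = 2.82e-07). Without the doubted libraries, the count was 1411 for antibiotics in colon, 2 in liver and 0 in colon for the light cycle with antibiotics, and on chow 549 in liver, 13 in colon, 0 in spleen and 1 in mammary gland. This left 1 LD12/12 library in spleen and in jejunum, assumed to vary like the other groups. In jejunum the mitochondrially encoded list then turned upward at LD0/24 (adjusted p = 0.0402), LD16/8 (adjusted p = 4.56e-10) and LD24/0 (adjusted p = 4.89e-06), since 2 of the 3 LD12/12 libraries were left out.

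Leaving out 1 library at a time gave 5233 to 6042 calls for antibiotics in liver. In hypothalamus the antibiotics calls ran from 2052 (without chow LD12/12 replicate 1) to 5705 (without chow LD12/12 replicate 3), with 2104 without antibiotics LD0/24 replicate 2 and 4908 without chow LD16/8 replicate 1. In colon they ran from 499 (without chow LD0/24 replicate 2) to 1411 (without antibiotics LD8/16 replicate 1). The chow light cycle count in liver ran from 13 (without chow LD0/24 replicate 2) to 283 (without chow LD16/8 replicate 6) and moved by more than 1.5 times for 47 of 60 libraries. The count ran from 0 to 96 in inguinal fat (96 without LD16/8 replicate 3, 4 without LD8/16 replicate 1 and 4 without replicate 3), from 0 to 13 in colon (without antibiotics LD8/16 replicate 1), from 0 to 3 in jejunum (without LD0/24 replicate 3) and from 0 to 3 in cecum (without LD8/16 replicate 2). In spleen it was 8348 without LD12/12 replicate 1 and 0 without any of the other 14 libraries, and in mammary gland it ran from 1 (without LD16/8 replicate 1) to 84 (without LD8/16 replicate 1) and moved for 11 of 15. In thymus it was 7 without LD0/24 replicate 1, 2 without LD16/8 replicate 1 and otherwise 0, and in hypothalamus and ileum it was 0 throughout. The light cycle count with antibiotics ran from 0 to 10 in liver (10 without antibiotics LD16/8 replicate 3), from 0 to 21 in hypothalamus (21 without antibiotics LD16/8 replicate 1) and from 0 to 27 in colon (27 without antibiotics LD8/16 replicate 2), and moved for 43 of 60, 25 of 30 and 28 of 30 libraries. The interaction count ran from 0 to 4 in liver (without chow LD16/8 replicate 6), from 0 to 1 in hypothalamus (without antibiotics LD16/8 replicate 1) and from 0 to 8 in colon (without antibiotics LD8/16 replicate 2). The count over several tissues stayed at 0, also at an adjusted p under 0.01. The ribosomal list in chow hypothalamus at LD8/16, whose adjusted p ran from 6.02e-13 to 0.00346, turned its direction without chow LD12/12 replicate 3 (adjusted p = 0.000165).

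The replicate number was also fitted as a block, although the labels do not say what it marks. The mean correlation of deviations between libraries with the same number lay between -0.03 and 0.1 by tissue, and not every pair was over 0.1. It was 0.1 in jejunum and in spleen, against -0.05 between libraries with different numbers. Libraries that correlated best with their own number were 10 of 60 in liver, 10 of 30 in hypothalamus, 10 of 30 in colon, 10 of 15 in inguinal fat, 10 of 15 in mammary gland, 7 of 15 in jejunum, 7 of 15 in spleen, 4 of 15 in cecum, 2 of 15 in ileum and 2 of 15 in thymus. Some best matches arise by chance, and these numbers were not tested against that rate. A pairing by number is therefore not excluded, above all in inguinal fat, mammary gland, jejunum and spleen. With the block 0 genes passed for the light cycle with antibiotics in liver, hypothalamus and colon, and on chow 0 in liver, 0 in spleen, 7 in inguinal fat, 1 in jejunum and 16 in mammary gland, with Smc6 at an adjusted p of 0.0763. The antibiotics effect had 5187, 3009 and 625 calls in liver, hypothalamus and colon.

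Of the named gene results, 147 of 150 stayed on their side of the threshold with DESeq2 size factors, 128 of 150 without a filter, 64 of 68 with a mean CPM of at least 10, 100 of 142 with DESeq2, 114 of 150 with limma-voom, 118 of 150 with the block, 142 of 150 with the other quasi-likelihood version, 143 of 146 with values divided by 4 and 8 of 17 with chow libraries only. The numbers were 134, 121 and 125 of 150 with the mitochondrial, library total and clock covariates, 12 of 37 with the Hox score, 83 of 102 without doubted libraries, 6 of 6 with the identical columns and 4402 of 4830 over single left-out libraries. Those that changed lost the call in 34 cases with limma-voom, 29 with the library total and 19 with the Hox score, and gained it in 42 cases with DESeq2. Of 39 named list results 36 lost the call with an estimated correlation, 8 with the mitochondrial share and 1 with DESeq2, and leaving out 1 library ended 1 of 1035.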

Other observations

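Among the tests in this part, that of the spleen calls without the LD12/12 libraries with over 50% mitochondrial counts, those of chow cell type and immediate-early lists with 1 library left out, and those of Dbp against Arntl and of their ratio against the mitochondrial share outside liver were chosen only after the result was seen. In antibiotics livers some genes of fasting and of sex-biased metabolism differed while their lists were not called. Pck1, the rate-limiting enzyme of gluconeogenesis, rose from 546 ± 315 to 1220 ± 829 CPM (n = 30 per diet, 1.25 ± 0.22 on the log2 scale, SE, adjusted p = 1.75e-05, higher in 24 of 30), and of 14 genes of gluconeogenesis and fasting 6 rose and 1 fell (the same numbers adjusted over the list alone, camera adjusted p = 0.0691, adjusted p = 0.915 with an estimated correlation). Of 21 sex-biased liver genes 6 rose and 7 fell (the same numbers adjusted over the list alone, adjusted p = 0.371, adjusted p = 0.946 with an estimated correlation). The list test looks for 1 common direction and does not use the sex to which each gene is biased. It therefore cannot decide whether male-biased and female-biased genes moved in opposite directions. Cyp2d9 rose from 13.7 ± 4.28 to 32.2 ± 11.5 CPM (adjusted p = 2.96e-12, higher in 30 of 30), while A1bg fell from 1080 ± 595 to 204 ± 184 CPM (adjusted p = 3.68e-10) and Cyp3a41a from 3300 ± 1530 to 1550 ± 294 CPM (adjusted p = 2e-10), both lower in 30 of 30. In colon Muc2, the main mucin of goblet cells, fell from 1510 ± 963 to 215 ± 136 CPM (n = 15 per diet, adjusted p = 5.53e-05, lower in 15 of 15), while Tff3, a goblet cell peptide, rose from 115 ± 51.2 to 512 ± 452 CPM (adjusted p = 0.00335, higher in 12 of 15), and of 10 goblet cell genes 2 rose and 2 fell (the same numbers adjusted over the list alone, adjusted p = 0.985, adjusted p = 0.997 with an estimated correlation). Of the genes called in both liver and hypothalamus, 605 went in opposite directions where independent lists would give 391.9, 103 were higher in both (138.9) and 144 lower in both (276.3). For liver and colon the numbers were 86 (73.6), 24 (23.2) and 83 (57.3), and for hypothalamus and colon 45 (41.8), 11 (12.2) and 26 (35.1). Tissues share no libraries, and the excess over independent lists was not tested.

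On chow, lists of immune and neighbouring cell types differed between cycles in several tissues, but 0 of their members passed over all genes with edgeR, and none of the calls given here held with an estimated correlation. In cecum, B cell genes were lower than at LD12/12 at LD8/16 (12 of 12 adjusted over the list alone, camera adjusted p = 6.65e-10, median log2 fold change -7.23) and at LD16/8 (12 of 12, adjusted p = 2.99e-10, median -6.09), with MHC class II genes (8 and 7 of 8, adjusted p = 5.58e-09 and 7.09e-08) and T cell genes (10 and 5 of 12, adjusted p = 1.36e-08 and 3.49e-07) lower as well, and an adjusted p of 0.456 for each with an estimated correlation. These cecum lists stayed called without any single library of the cycles compared, although in several such fits 0 T cell genes passed over the list alone. In jejunum B cell genes were higher at LD8/16 (12 of 12 adjusted over the list alone, adjusted p = 0.00133, adjusted p = 0.821 with an estimated correlation), but the list was not called without LD8/16 replicate 3 (adjusted p = 0.666, direction downward), and 0 of 12 passed over the list alone without any 1 of the LD12/12 libraries. In inguinal fat skeletal muscle genes were higher at LD24/0 (11 of 13 adjusted over the list alone, adjusted p = 1.1e-22, adjusted p = 0.112 with an estimated correlation), with Tnnt3, a fast muscle troponin, at 74.2 ± 123 CPM and a range from 1.07 to 216 CPM, against 0.252 ± 0.149 CPM at LD12/12 (n = 3), and without LD24/0 replicate 2 none of the members passed when adjusted over the list alone, while the list was still called (adjusted p = 1.82e-12). Milk genes were higher in inguinal fat at LD16/8 (12 of 12 adjusted over the list alone, adjusted p = 5.24e-09, adjusted p = 0.6 with an estimated correlation), but this rested on replicate 1, in which Csn2 took 16.4% of counts: Csn2 was at 4.62 and 1.59 CPM in the other LD16/8 libraries, and without replicate 1 the list was not called (adjusted p = 0.307). In spleen 13 of 16 genes of pancreatic acinar cells differed among the cycles when adjusted over the list alone and 0 over all genes, and the list was called upward at LD16/8 (adjusted p = 0.0388, adjusted p = 0.721 with an estimated correlation), but not without LD12/12 replicate 1 (adjusted p = 0.74) or LD16/8 replicate 2 (adjusted p = 0.305). In liver immediate-early genes were higher at LD24/0 (6 of 18 adjusted over the list alone, adjusted p = 1.03e-07, adjusted p = 0.182 with an estimated correlation).

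Dbp and Arntl went in opposite directions within groups. Over 60 liver libraries, as deviations from group means of log2 CPM, r was -0.94 and rho -0.95 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give, adjusted p = 0.0001 over a family of 10 tissues), and r was -0.94 without the 2 farthest libraries. In hypothalamus (n = 30) r was -0.72 and rho -0.67 (permutation p = 0.00057 and 0.0007, adjusted p = 0.00142, r = -0.69 without the 2 farthest). In colon (n = 30) r was -0.67 and rho -0.77 (permutation p = 0.0001 and 8e-05, adjusted p = 0.000333, r = -0.7 without them). With 15 libraries each, r was -0.94 in inguinal fat, -0.88 in ileum, -0.96 in jejunum and -0.94 in cecum, rho was -0.95, -0.85, -0.88 and -0.97, and r without the 2 farthest was -0.92, -0.81, -0.96 and -0.93. The permutation p of r was 0.00072, 0.00207, 0.00101 and 0.0001 in these 4 tissues, that of rho 0.0005, 0.00806, 0.00666 and 0.0001, and the adjusted p of r 0.00144, 0.00296, 0.00168 and 0.000333. In spleen, mammary gland and thymus r was -0.43, -0.36 and -0.28, rho was -0.24, -0.44 and -0.3, and r without the 2 farthest was 0.15, -0.15 and -0.22. The permutation p of r was 0.413, 0.314 and 0.362 and that of rho 0.49, 0.208 and 0.345 (adjusted p of r 0.413, 0.392 and 0.402). The Dbp to Arntl ratio, again as deviations from group means, was also set against the mitochondrial share in the 10 tissues, and 0 relations passed after adjustment. In jejunum, cecum and spleen (n = 15 each) r was 0.49, -0.31 and -0.9, rho was 0.56, -0.32 and -0.54, and r without the 2 farthest was 0.31, -0.05 and -0.62. The permutation p of r was 0.114, 0.548 and 0.141 and that of rho 0.0989, 0.389 and 0.133, with an adjusted p of r of 0.705, 0.978 and 0.705. In the other 6 tissues besides liver, r lay between -0.02 and 0.12 and rho between -0.03 and 0.09, with a permutation p of r between 0.635 and 0.978 and of rho between 0.801 and 0.935 (adjusted p of r 0.978 for each). Without the 2 farthest libraries r was -0.04 in hypothalamus, -0.39 in inguinal fat, -0.09 in ileum, 0.02 in colon, 0.4 in mammary gland and -0.07 in thymus.

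Libraries were also regrouped at random into groups of the same sizes, with 100 splits drawn per test and 60 in colon, the real one included. For antibiotics chance can be excluded in liver (1 of 100 splits called at least as many genes as the real 5562, the highest other 725), hypothalamus (1 of 100, real 3267, highest other 933) and colon (1 of 60, real 761, highest other 11). For the light cycle on chow in spleen, 4 of 100 splits called at least as many genes (real 26, highest other 2147). That share is under 0.05 for this tissue taken alone. As 10 tissues were tested without adjustment over them, chance is not excluded in spleen. Without the 2 LD12/12 spleen libraries with over 50% mitochondrial counts 0 calls were left, but that fit held 1 LD12/12 library, assumed to vary like the other groups, and the 26 calls also fell to 0 without any 1 of 14 of the 15 libraries. For the spleen calls, an effect of these 2 libraries and one of the light cycle therefore cannot be told apart. Chance cannot be excluded in liver (40 of 100, real 47, highest other 5805) or mammary gland (10 of 100, real 3, highest other 14). In tissues with 0 real calls all splits count as being as large: 100 of 100 in hypothalamus (highest other 2746), inguinal fat (464), ileum (2661), jejunum (183), cecum (449) and thymus (665), and 60 of 60 in colon (1). Among antibiotics libraries, chance cannot be excluded in liver (100 of 100, real 1, highest other 54), hypothalamus (14 of 100, real 4, highest other 10) or colon (42 of 60, real 5, highest other 190). For the interaction, with 0 real calls, the numbers were 100 of 100 in liver (highest other 2413), 100 of 100 in hypothalamus (2) and 60 of 60 in colon (1). The highest other split called several times the real number for the light cycle on chow in liver, spleen and mammary gland and with antibiotics in liver and colon, which points to some structure among the libraries. This rests on the highest split of each test, and no such structure was tested. Where the real count was 0, no multiple of it can be given.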
